A study of Caenorhabditis elegans with 35 samples.

How the data were processed

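Gene expression was measured on arrays in 35 RNA preparations from whole Caenorhabditis elegans larvae of the L3 stage. The animals were F4 or F5 generation, and each generation held 3 groups: wild type descended from wild type (+/+ from +/+), genetically wild type animals descended from wdr-5 mutants (+/+ from wdr-5), and wdr-5 homozygous mutants. Every group had 6 arrays except F5 +/+ from wdr-5, which had 5. The labels give each array 1 of 2 birth days, and both birth days held arrays of all 6 groups.

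The deposited values are log2 intensities made by the authors with robust multi-array averaging (RMA), per the submitters' processing notes. The values are normalized and log transformed, per the file headers. Neither source states the base of the logarithm or the software version, and base 2 was read from the range of the values. The deposited values of the birth days have different spreads, with a 5th percentile of 3.04 to 3.23 on the 17 arrays of birth day 1 and of 4.12 to 4.21 on the 18 arrays of birth day 2. The days were therefore taken to have been normalized separately, and the reported comparisons were made within a birth day or with a birth day term. The exceptions are an alternative fit without that term and the ratios for outlying arrays, which used deposited values of both days. The series value table and the tables per birth day held the same values for the probe sets they share, with a largest difference of 0, and only the tables per day held the 77 control probe sets. No array was left out. Quantile normalization over all arrays, tried as an alternative, moved the median of an array by at most 0.086. Medians of the days already overlapped, at 5.35 to 5.50 on birth day 1 and 5.37 to 5.48 on birth day 2. The shift of low values, where the days differ, was not measured.

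All 20806 probe sets of the series table that are not controls were tested. The reference gene table named 15504 probe sets by their transcript accession, and 4660 more by matching the symbol in the deposited tables. A further 510 kept the deposited symbol alone and 132 had no gene name. On all arrays, 1937 probe sets repeated the values of another, which left 18869 distinct ones, and counts of probe sets hold these repeats. Values identical on all arrays under several gene names occurred in 123 probe sets, and none of these was used to name a gene. For tests of gene lists, each of the 17236 genes with an unambiguous probe set was represented by the probe set of highest mean over all arrays.

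Differences were fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3. The model held the 6 groups and the birth day within each generation, so that all arrays shared 1 estimate of the spread per probe set with 27 residual degrees of freedom. Tests were two-sided, and p-values were adjusted over the 20806 probe sets by Benjamini-Hochberg, with a threshold of 0.05. The 6 direct comparisons were +/+ from wdr-5 against +/+ from +/+, mutant against +/+ from +/+, and mutant against +/+ from wdr-5, in each generation. A further pair of contrasts tested whether the difference from +/+ from +/+ differed between F4 and F5. Whether a difference itself varied between the birth days was tested in a fit with its own mean for each group and day.

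The 26 gene lists cover H3K4 methylation machinery, small RNA pathways, insulin signalling, DAF-16 up targets, DAF-16 down targets, heat shock and chaperones, lipid metabolism, glycolysis and central carbon, respiratory chain, detoxification, innate immunity, vitellogenins, cuticle collagens, moulting cycle, adult stage, germline, sperm, oocyte and eggshell, muscle, neuron, intestine, pharyngeal gland and cells, dauer and developmental arrest, ribosomal proteins, histones and longevity regulators. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 104 tests (26 lists in the 4 comparisons against +/+ from +/+). Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted after adjustment over all probe sets and also adjusted over the list alone.

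Genes were named by a rule. It took the 10 largest rises and 10 largest falls among probe sets past the threshold whose difference had the same sign on both birth days, or 5 of each for mutant against +/+ from wdr-5 and for the contrasts between generations. Where fewer than 3 probe sets passed, it took the 5 smallest p-values. It also took wdr-5.1, wdr-5.2 and wdr-5.3 in all comparisons and up to 4 members of each list by smallest p. Probe sets with no gene name or with several were not named, and a gene was named once per comparison by its probe set of highest mean. The text names the first 2 members of a list in the mutant comparisons and, in the comparisons of +/+ from wdr-5, only members of lists that camera called. This narrowing was made later.

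Correlations between the differences of +/+ from wdr-5 and of mutants were taken across probe sets between the birth days, so that no array entered both sides. The pooled correlation, which shares control arrays, is given beside 100 simulations of unchanged groups against shared controls. The fits, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were the replicate number as a block, each birth day alone, no birth day term, only the arrays of the groups compared, quantile normalization over all arrays, centring on array medians, leaving out dim probe sets, the other deposited table, no intensity trend, array weights, and leaving out each array in turn. Added after seeing the data were fits on means of a group and birth day, fits with an own mean per group and day, 1 probe set per gene, fits with axes of spread between arrays as covariates, and a comparison of the largest changes with the 25th percentile of each array.

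The code was tested on simulated data with planted changes. At a planted log2 difference of 0.5, the share recovered was 76.1% to 89.6% in the 6 direct comparisons and 56.7% and 58.2% in the contrasts between generations, with 6 to 15 false calls per comparison. The planted gene list was called and 0 other lists were. A built-in correlation of 0.798 was measured as 0.796. The simulated noise was independent between probe sets, so these values test the code and not the rate of false calls in the real arrays. There, random assignments of the arrays called a median of 35 gene lists. The number of arrays limits the precision: the median standard error of a log2 difference was 0.081 with 6 arrays a side and 0.085 where F5 +/+ from wdr-5 took part.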

Results

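The series profiled L3 larvae of 6 groups on 35 arrays, in 2 generations and on 2 birth days. The wdr-5.1 gene encodes a WD-repeat protein of the complexes that methylate lysine 4 of histone H3 (H3K4). The mutants were homozygous for a wdr-5 allele, and the +/+ from wdr-5 animals were wild type at the gene but had mutant ancestors. Arrays of the same group and birth day correlated at r = 0.973 to 0.997 across probe sets. Array medians ran from 5.35 to 5.50 log2.

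The wdr-5.1 transcript was low in the mutants and at the wild-type level in the descendants. Its level was 8.63 ± 0.18 log2 (SD, n = 6) in F4 +/+ from +/+, 8.59 ± 0.14 (SD, n = 6) in F4 +/+ from wdr-5 and 5.00 ± 0.66 (SD, n = 6) in F4 mutants. In F5 it was 8.53 ± 0.16 (SD, n = 6), 8.57 ± 0.18 (SD, n = 5) and 4.76 ± 0.31 (SD, n = 6). These means pool both birth days, whose value ranges differ, and each group holds both days. The mutant differences from +/+ from +/+ were -3.63 ± 0.14 (SE, adjusted p = 1.12e-18) in F4 and -3.77 ± 0.14 (SE, adjusted p = 4.21e-19) in F5. Of its paralogs, wdr-5.2 differed by 0.013 ± 0.064 (SE, adjusted p = 0.92) in F4 mutants and -0.11 ± 0.064 (SE, adjusted p = 0.19) in F5 mutants. The other paralog, wdr-5.3, rose by 0.81 ± 0.23 (SE, adjusted p = 0.0084) in F5 mutants and differed by 0.27 ± 0.23 (SE, adjusted p = 0.46) in F4 mutants. The F5 rise was uneven between arrays. The level of wdr-5.3 was 7.72, 7.43 and 8.01 log2 in mutant replicates 1, 4 and 5, 6.63 and 6.51 in replicates 2 and 3 and 7.16 in replicate 6. Controls lay at 6.22 to 6.51 in +/+ from +/+ on birth day 1 (replicates 1 to 3) and 6.37 to 6.58 on birth day 2. The rise was not past the threshold on birth day 1 alone (0.58, adjusted p = 0.094) or with the leading axis of spread among the mutant arrays as a covariate (0.19, adjusted p = 0.34). The difference of wdr-5.3 between the generations was not past the threshold (-0.54 ± 0.33, SE, adjusted p = 0.47).

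**Figure D1:**
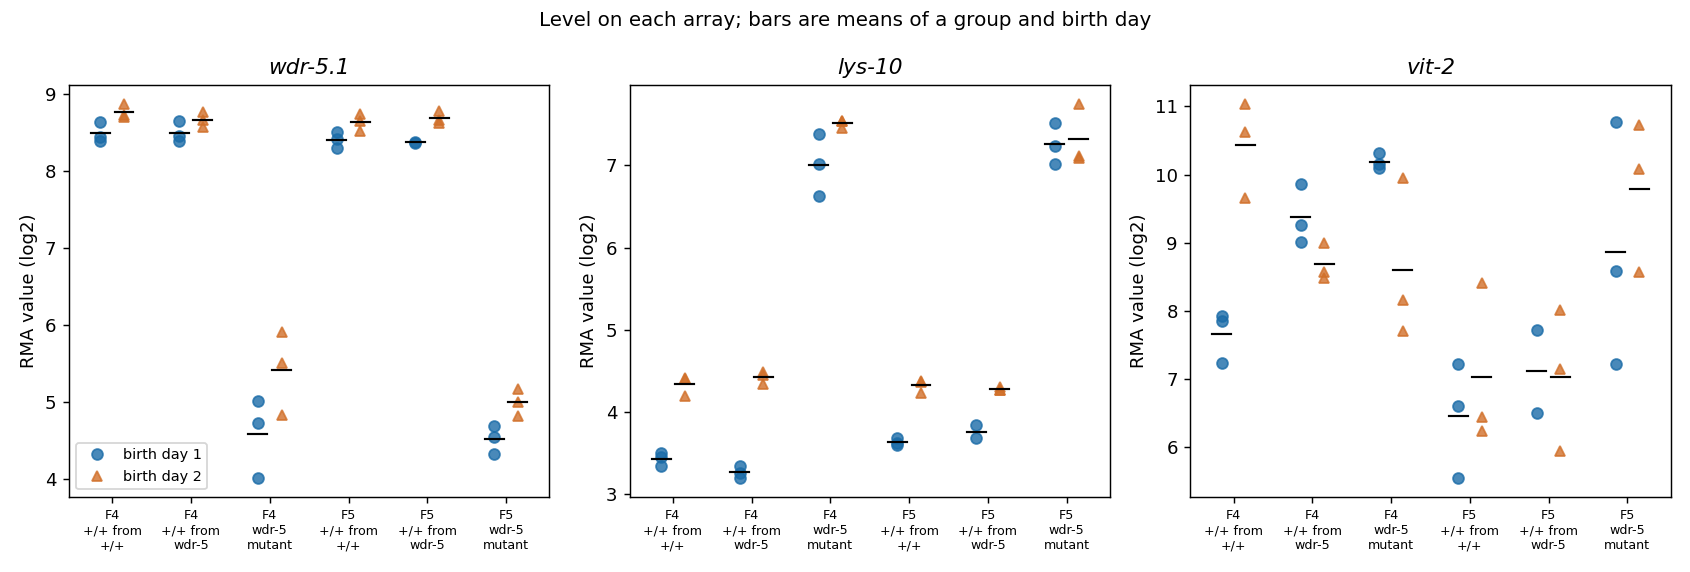
RMA values (log2) of wdr-5.1, lys-10 and vit-2 on each of the 35 arrays, by group; circles are birth day 1, triangles birth day 2, and bars the mean of a group and birth day. Mutant means of wdr-5.1 over both days were 5.00 and 4.76, mutant means of lys-10 were 7.26 and 7.29, and vit-2 in F4 mutants lay above its same-day controls on birth day 1 and below their mean on birth day 2.

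The comparison of F4 +/+ from wdr-5 with F4 +/+ from +/+ asks whether wild-type descendants of mutants differ in expression from animals without mutant ancestors. No gene passed the threshold in either direction over both birth days. The 5 genes of smallest p were mam-2 (0.55 ± 0.12, SE), the cytochrome P450 gene cyp-35A5 (0.27 ± 0.061), the cathepsin gene cpz-1 (0.29 ± 0.075), the acyltransferase gene oac-30 (0.29 ± 0.077) and cwp-2 (-0.15 ± 0.038), with adjusted p from 0.78 to 0.9986. The wdr-5.1 difference was -0.043 ± 0.14 (SE), that of wdr-5.2 was 0.033 ± 0.064 and that of wdr-5.3 was -0.078 ± 0.23. With limma, 0 of 20806 probe sets passed and 750 had an unadjusted p under 0.05. These are 3.60%, where unchanged groups would give a share of about 0.05. The test was thus cautious here, and the count of 0 does not show that the groups are equal.

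At its preset correlation, camera called 3 lists in F4 +/+ from wdr-5, which were moulting cycle, cuticle collagens and sperm. None of their members was called over all probe sets. Of the 47 measured moulting cycle genes, which oscillate with the larval moults, 0 rose, 0 fell and 47 were not called, and 1 rose adjusted over the list alone. Their median difference was 0.14, with camera adjusted p = 1.58e-12 and adjusted p = 0.40 with an estimated correlation. The members of smallest p were ptr-18, a patched-related gene (0.46 ± 0.13, SE), and qua-1, a hedgehog-related gene (0.33 ± 0.12). Cuticle collagens had 0 of 110 members called and a median of 0.058, with camera adjusted p = 2.75e-04 and adjusted p = 0.98 with an estimated correlation; dpy-5 differed by 0.17 ± 0.059 (SE) and col-73 by 0.14 ± 0.046. Sperm genes had 0 of 33 members called and a median of 0.13, with camera adjusted p = 8.40e-05 and adjusted p = 0.98 with an estimated correlation; spe-4 differed by 0.26 ± 0.13 (SE) and spe-44 by 0.15 ± 0.10. None of the 3 calls kept its side of the threshold with an estimated correlation, and in 88 of 100 random assignments of the arrays at least as many lists were called over the 4 comparisons as the real 22. The other 23 lists had 0 members called, camera adjusted p of at least 0.0696, and medians from -0.11 to 0.11; over all lists, 2 members rose adjusted over the list alone, of which 1 was in detoxification. Median, mean and test had the same sign in the 3 called lists and differed in sign in 11 others.

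The difference between F4 +/+ from wdr-5 and F4 +/+ from +/+ had opposite signs on the birth days in several lists. The vitellogenins, yolk proteins of the adult intestine, had a median difference of 1.28 on birth day 1 and -1.45 on birth day 2, and oocyte and eggshell genes 0.56 and -0.79. Adult stage genes had medians of 0.88 and -0.61, sperm genes 0.55 and -0.26, germline genes 0.17 and -0.24, and moulting cycle genes -0.073 and 0.32. Across all probe sets the differences of the days had r = -0.616, where genes are not independent replicates. On the leading axis of spread among F5 mutant arrays, +/+ from +/+ scored -18.032 to -7.20 on birth day 1 and 19.7 to 34.3 on birth day 2, and +/+ from wdr-5 scored 1.29 to 14.2 and 5.53 to 9.43. Levels of vit-2 were 7.23 to 7.92 and 9.66 to 11.04 log2 in +/+ from +/+ and 9.01 to 9.86 and 8.49 to 8.99 in +/+ from wdr-5. Which group changed between the days cannot be read from this, since values of the days have different ranges and F5 +/+ from +/+ also scored higher on birth day 2. A test of the difference between the days called 377 probe sets. The same fit called 56 higher and 99 lower probe sets on birth day 1 and 34 higher and 14 lower on birth day 2, and the days fitted alone called 9 and 10.

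The comparison of F5 +/+ from wdr-5 with F5 +/+ from +/+ asks the same of animals a generation later. No gene passed here either. The smallest p-values belonged to K12C11.6 (0.36 ± 0.11, SE), srbc-17 (-0.18 ± 0.055), the carboxylesterase gene cest-30 (0.15 ± 0.047), C35E7.3 (0.11 ± 0.036) and sru-3 (-0.14 ± 0.045), with srbc-17 and sru-3 encoding serpentine receptors, and all had an adjusted p of 0.999997. Differences were 0.0049 ± 0.15 (SE) for wdr-5.1, -0.0073 ± 0.068 for wdr-5.2 and 0.018 ± 0.25 for wdr-5.3. With limma, 0 of 20806 probe sets passed and 210 had an unadjusted p under 0.05. These are 1.01%, where unchanged groups would give a share of about 0.05. The SD of the differences across probe sets was 0.069, under their median standard error of 0.085. The shared spread thus made the test cautious, and the count of 0 does not show that the groups are equal. Camera called 0 of the 26 lists, list medians ran from -0.069 to 0.20, and 0 members were called over all probe sets or adjusted over the list alone. Day 1 fitted alone called 2 probe sets, both of the collagen IV gene let-2, which was named after its value was seen. Both hold the same values and are a single measurement. Day 2 alone called 0 with limma, where 469 had an unadjusted p under 0.05.

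Whether the descendants differed more in F4 than in F5 was tested directly. The genes of smallest p were oac-30 (0.44 ± 0.11, SE), cwp-2 (-0.20 ± 0.056), dpt-1 (0.80 ± 0.24), the galectin gene lec-8 (-0.34 ± 0.10) and F37H8.2 (-0.20 ± 0.060), each F4 minus F5 with an adjusted p of 0.9996. With limma, 0 probe sets passed, and 350 (1.68%) had an unadjusted p under 0.05, so this test was cautious as well. The contrasts were -0.048 ± 0.21 for wdr-5.1, 0.041 ± 0.093 for wdr-5.2 and -0.096 ± 0.34 for wdr-5.3.

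F4 wdr-5 mutants against F4 +/+ from +/+ gives the mutant difference beside which the descendants are read. The lysozyme gene lys-10 of the innate immunity list was higher in mutants, with a fitted difference of 3.37 ± 0.13 log2 (SE, adjusted p = 4.64e-19). Its control values of 3.35 to 3.50 on birth day 1 and 4.20 to 4.42 on birth day 2 lay under the 25th percentile of all 6 arrays, so the size of this rise and its rank depend on a background that was not assessed. The other large rises were in W08E12.2 (2.37 ± 0.29, SE), far-3, which encodes a fatty acid and retinol binding protein (2.04 ± 0.19), C50F7.5 (1.96 ± 0.28), C01G10.5 (1.96 ± 0.37), dod-3, a gene downstream of the FOXO factor DAF-16 (1.80 ± 0.24), C36C5.14 (1.69 ± 0.25), lea-1, a late embryogenesis abundant protein gene (1.59 ± 0.17), C01G10.17 (1.58 ± 0.29) and C50F4.6 (1.57 ± 0.14). Below wdr-5.1, the largest falls were in the aspartyl protease gene asp-12 (-2.36 ± 0.20, SE), Y49E10.4 (-1.80 ± 0.11), the infection response gene irg-4 (-1.59 ± 0.15), F42A9.6 (-1.32 ± 0.12), F32D8.12 (-1.32 ± 0.11), F42A10.7 (-1.29 ± 0.13), the glucuronosyltransferase gene ugt-19 (-1.29 ± 0.19), the F-box gene fbxa-107 (-1.24 ± 0.14) and M04C9.3 (-1.17 ± 0.12). All 6 mutant arrays lay beyond every same-day control in 9 of the 10 largest rises (4 arrays for C01G10.5) and in 10 of the 10 largest falls. Control values also lay under the 25th percentile in 2 of 6 arrays for C01G10.5 and C01G10.17. Mutant values did so in 3 of 6 for ugt-19 and 2 of 6 for fbxa-107. The sizes and ranks of these changes are uncertain too.

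Part of the histone genes rose in F4 mutants. Of 28 measured members 8 rose, 0 fell and 20 were not called, with 10 rises adjusted over the list alone. On birth day 1 alone 7 rose and 3 fell (median 0.096), and on day 2 13 rose and 2 fell (median 0.41). Their median over both days was 0.20, with camera adjusted p = 6.44e-07 and adjusted p = 0.15 with an estimated correlation. The histone genes his-59 and his-38 were the members of smallest p, with rises of 0.74 ± 0.098 (SE) and 0.62 ± 0.086. Among genes raised by DAF-16 in long-lived insulin receptor mutants (DAF-16 up targets), 8 of 25 rose, 1 fell and 16 were not called, or 9 and 2 adjusted over the list alone, with camera adjusted p = 0.0143 and adjusted p = 0.56 with an estimated correlation. The glyoxylate cycle gene icl-1 fell against the direction of that list (-0.88 ± 0.10, SE). Genes lowered by DAF-16 had 0 rises and 2 falls among 15, the same adjusted over the list alone, in dod-17 (-0.91 ± 0.12) and dod-22 (-0.36 ± 0.091), with camera adjusted p = 0.667.

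Metabolic lists of F4 mutants held members of both signs, and their medians changed sign between the birth days. On days 1 and 2 these were -0.034 and 0.19 for the respiratory chain, -0.21 and 0.15 for lipid metabolism, -0.19 and 0.11 for glycolysis and central carbon, -0.10 and 0.036 for detoxification and -0.063 and 0.016 for chaperones. In the respiratory chain list 7 of 37 members rose, 1 fell and 29 were not called (11 and 2 adjusted over the list alone), with cox-5B up by 0.20 ± 0.034 (SE) and ucr-2.3 down (-0.56 ± 0.067); camera adjusted p = 0.0015, and adjusted p = 0.98 with an estimated correlation. Lipid metabolism had 5 rises and 6 falls among 60 (5 and 6 adjusted over the list alone), with falls of the acyl-CoA synthetase gene acs-2 (-0.74 ± 0.12) and the acyl-CoA dehydrogenase gene acdh-2 (-1.05 ± 0.17). Glycolysis and central carbon had 1 rise and 4 falls among 35 (1 and 4 adjusted over the list alone), with sucg-1 of the citric acid cycle at -0.54 ± 0.071. Detoxification had 11 rises and 12 falls among 85 (14 and 18 adjusted over the list alone), with the glutathione transferase genes gst-6 at -0.84 ± 0.10 and gst-39 at 0.54 ± 0.076. Chaperones had 3 rises and 4 falls among 23 (3 and 5 adjusted over the list alone), with the mitochondrial chaperones hsp-60 (-0.58 ± 0.095) and hsp-6 (-0.43 ± 0.082) both lower. Camera adjusted p was 0.92, 0.567, 0.811 and 0.756 for these 4 lists.

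Medians of most regulatory, immune and stress lists of F4 mutants changed sign between the birth days. On days 1 and 2 they were 0.23 and -0.18 for small RNA pathways, -0.13 and 0.18 for innate immunity, -0.11 and 0.064 for insulin signalling, -0.18 and 0.039 for dauer and developmental arrest and -0.14 and 0.053 for longevity regulators. H3K4 methylation machinery kept its sign (0.21 and 0.019). Innate immunity had 11 rises, lys-10 first, and 9 falls among 75 (15 and 9 adjusted over the list alone, camera adjusted p = 0.082). H3K4 methylation machinery had 1 rise, in the demethylase gene utx-1 (0.27 ± 0.072, SE), and 1 fall, wdr-5.1 itself, among 17 (4 and 1 adjusted over the list alone, camera adjusted p = 0.246). Small RNA pathways had 4 rises and 3 falls among 32 (4 and 3 adjusted over the list alone, camera adjusted p = 0.466), with the RNA-dependent RNA polymerase gene rrf-2 up by 0.57 ± 0.11 and the nuclear RNAi gene nrde-2 by 0.34 ± 0.070. Insulin signalling had 2 rises and 1 fall among 32 (2 and 1 adjusted over the list alone, camera adjusted p = 0.451), with the insulin-like peptide gene ins-35 at 0.97 ± 0.20 and the kinase gene akt-2 at -0.33 ± 0.088. Dauer and developmental arrest had 3 rises, scl-2 among them (1.18 ± 0.14), and 2 falls among 35 (3 and 4 adjusted over the list alone, camera adjusted p = 0.537). Longevity regulators had 1 rise, the transcription factor gene pqm-1 (0.78 ± 0.13), and 0 falls among 30 (1 and 0 adjusted over the list alone, camera adjusted p = 0.672), and pha-4 differed by -0.28 ± 0.099 without passing (adjusted p = 0.0645).

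Tissue and stage lists of F4 mutants had medians of opposite sign on the birth days, except pharyngeal gland and cells (-0.22 and -0.11). Intestine had 5 rises, among them the lysozyme gene lys-7 (1.23 ± 0.19, SE), and 12 falls, among them the protease gene asp-1 (-0.32 ± 0.038), of 52 members (9 and 13 adjusted over the list alone, camera adjusted p = 0.143). Muscle had 1 rise and 7 falls among 46 (2 and 8 adjusted over the list alone, camera adjusted p = 0.108), with the twitchin gene unc-22 at -0.42 ± 0.084 and the troponin gene tnt-3 at -0.58 ± 0.12. Neuron had 3 rises and 3 falls among 86 (3 and 3 adjusted over the list alone, camera adjusted p = 0.537), with the synaptobrevin gene snb-1 at 0.39 ± 0.047 and the neuropeptide gene nlp-11 at 0.52 ± 0.13. Pharyngeal gland and cells had 0 rises and 4 falls among 26 (0 and 6 adjusted over the list alone), pqn-74 among them (-0.57 ± 0.15); camera adjusted p = 0.0088, and adjusted p = 0.98 with an estimated correlation. Moulting cycle genes had 0 rises and 6 falls among 47 (0 and 6 adjusted over the list alone, camera adjusted p = 0.169), with phat-4 at -0.71 ± 0.16 and mlt-10 at -0.53 ± 0.13. Cuticle collagens had 7 rises, col-176 (0.42 ± 0.12) and dpy-17 (0.28 ± 0.082) among them, and 1 fall among 110 (0 and 0 adjusted over the list alone, camera adjusted p = 0.413).

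Reproductive genes of F4 mutants were called in small numbers. Sperm genes had 3 rises, with the kinase gene spe-6 at 0.69 ± 0.16 (SE), and 1 fall, in the translational regulator gene cpb-1 (-0.41 ± 0.068), among 33 (7 and 1 adjusted over the list alone); camera adjusted p = 3.18e-04, and adjusted p = 0.98 with an estimated correlation. Oocyte and eggshell genes had 2 rises, skr-1 (0.33 ± 0.075) and the caveolin gene cav-1 (0.94 ± 0.24), and 0 falls among 30 (2 and 0 adjusted over the list alone); camera adjusted p = 0.0143, and adjusted p = 0.98 with an estimated correlation. Germline genes had 0 rises and 1 fall, cpb-1, among 55 (0 and 1 adjusted over the list alone, camera adjusted p = 0.837), and the meiotic gene htp-2 differed by 0.36 ± 0.12 without passing (adjusted p = 0.055). Vitellogenins had 0 of 6 called (0 adjusted over the list alone, camera adjusted p = 0.773), with vit-1 at 0.54 ± 0.43 and vit-2 at 0.34 ± 0.62. Adult stage genes had 0 of 20 called (0 adjusted over the list alone, camera adjusted p = 0.354), with the sperm gene msp-76 at 0.50 ± 0.32 and the oocyte gene oma-1 at 0.42 ± 0.27. Ribosomal protein genes had 0 of 66 called (0 adjusted over the list alone) and a median of 0.019, with rpl-15 at 0.077 ± 0.029 and rla-1 at -0.070 ± 0.025; camera adjusted p = 0.0176, and adjusted p = 0.98 with an estimated correlation.

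These low counts stood over medians that changed sign between the birth days. Medians on birth days 1 and 2 were 1.80 and -1.84 for vitellogenins, 1.58 and -0.95 for oocyte and eggshell genes, 1.61 and -0.88 for adult stage genes, 1.29 and -0.36 for sperm genes and 0.32 and -0.35 for germline genes. Histones kept 1 sign, with medians of 0.096 and 0.41. The differences of the days in F4 mutants had r = -0.383 across probe sets. In total 2142 probe sets passed in F4 mutants, 992 higher and 1150 lower. The higher share was 46.3%, against 38.2% with arrays centred on their medians and 45.7% with quantile normalization. More were higher than lower with array weights (1143 and 883), on birth day 2 alone (1362 and 1133) and with the stage axis, the leading axis of spread among F5 mutant arrays, as a covariate (2079 and 1689). The difference between the days was past the threshold in 6856 probe sets, and birth days fitted alone called 6335 and 2495. Leaving out replicate 2 of F4 +/+ from +/+ left 1403 calls and leaving out replicate 1 left 1421; the calls of dpy-17, akt-2, utx-1 and col-176 each ended without some single array. A fit on the means of each group and birth day called 11. With the stage axis as a covariate, rises and falls went from 3 and 3 to 18 and 3 in neuron, from 7 and 1 to 15 and 1 in the respiratory chain and from 11 and 9 to 22 and 9 in innate immunity. Detoxification went from 11 and 12 to 18 and 15. Tissue lists went from 5 and 12 to 13 and 14 in intestine, from 7 and 1 to 12 and 15 in cuticle collagens and from 0 and 1 to 4 and 11 in germline. Sperm went from 3 and 1 to 8 and 2, and oocyte and eggshell from 2 and 0 to 6 and 1. Metabolic lists went from 1 and 4 to 6 and 5 in glycolysis and central carbon and from 5 and 6 to 9 and 8 in lipid metabolism. DAF-16 up targets went from 8 and 1 to 11 and 2 and histones from 8 and 0 to 11 and 0. The other lists changed by at most 3 members in a direction. Median, mean and test differed in sign in 6 lists, none of them called: H3K4 methylation machinery, chaperones, lipid metabolism, vitellogenins, cuticle collagens and germline. Among the 77 control probe sets, the 6 for dap, a bacterial transcript added as a labelling control, had median differences of 0.88 on birth day 1 and 0.64 on birth day 2, against 0.12 and 0.16 for the other 71.

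F5 wdr-5 mutants against F5 +/+ from +/+ asks the same in the next generation. The lysozyme gene lys-10 was again higher, with a fitted difference of 3.31 ± 0.13 log2 (SE, adjusted p = 4.21e-19). Its control values of 3.60 to 3.68 and 4.23 to 4.38 on the birth days lay under the 25th percentile of all 6 arrays, as did 5 of 6 for F53H4.2, so the sizes and ranks of these rises are uncertain. The cuticle collagen genes col-81 (3.01 ± 0.67, SE), col-129 (2.77 ± 0.55) and col-139 (2.75 ± 0.60) followed, with D1054.10 (2.93 ± 0.73), F53H4.2 (2.82 ± 0.68) and Y57G11B.5 (2.67 ± 0.70). The uterine lumen genes ule-3 (2.76 ± 0.70) and ule-4 (2.55 ± 0.47) and the yolk protein gene vit-2 (2.58 ± 0.62) completed the 10 largest rises. Below wdr-5.1, the largest falls were in Y49E10.4 (-1.99 ± 0.11, SE), irg-4 (-1.96 ± 0.15), F42A10.7 (-1.44 ± 0.13), F32D8.12 (-1.41 ± 0.11), the peptidyl-prolyl isomerase gene fkb-8 (-1.39 ± 0.13), cld-9 (-1.37 ± 0.17), dpt-1 (-1.24 ± 0.17), the glucuronosyltransferase gene ugt-16 (-1.23 ± 0.13) and K08B12.3 (-1.22 ± 0.12). All 6 mutant arrays lay beyond every same-day control in 9 of the 10 largest rises (5 arrays for vit-2) and in 10 of the 10 largest falls. Mutant values of dpt-1 lay under the 25th percentile in 2 of 6 arrays, so the size of its fall is uncertain.

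Reproductive and adult genes rose together in F5 mutants. These lists overlap, since the adult stage list also holds the vitellogenins and major sperm protein genes of the sperm list, so their counts are not separate results. Of the 30 oocyte and eggshell genes 26 rose, 1 fell and 3 were not called (27 and 1 adjusted over the list alone), with a median of 1.17; camera adjusted p = 2.03e-09, and adjusted p = 0.98 with an estimated correlation. Examples are the eggshell chitin synthase gene chs-1 (1.75 ± 0.30, SE) and the RNA-binding gene puf-11 (1.59 ± 0.29). Sperm genes had 27 rises, 1 fall and 5 not called among 33 (29 and 1 adjusted over the list alone), with ssp-31 at 1.72 ± 0.31 and spe-6 at 0.82 ± 0.16; camera adjusted p = 6.03e-08, and adjusted p = 0.98 with an estimated correlation. Germline genes had 33 rises, 2 falls and 20 not called among 55 (35 and 2 adjusted over the list alone), with the meiotic genes syp-2 (0.98 ± 0.13) and spo-11 (0.99 ± 0.15); camera adjusted p = 1.25e-08, and adjusted p = 0.98 with an estimated correlation. Adult stage genes had 17 rises, 1 fall and 2 not called among 20 (17 and 1 adjusted over the list alone), with the yolk receptor gene rme-2 at 1.52 ± 0.35 and oma-1 at 1.14 ± 0.27; camera adjusted p = 6.19e-05, and adjusted p = 0.98 with an estimated correlation. Vitellogenins rose in 6 of 6 (6 adjusted over the list alone), vit-6 by 2.09 ± 0.57, with a median of 1.99; camera adjusted p = 0.0069, and adjusted p = 0.98 with an estimated correlation. The mutant arrays stood in separate sets. On the leading axis of spread among them, replicates 1, 4 and 5 scored 36.6, 26.7 and 38.4, and replicates 2, 3 and 6 scored -16.102, -14.44 and -22.34. The +/+ from +/+ arrays scored -34.1 to -27.9 on birth day 1 (replicates 1 to 3) and -12.602 to -9.99 on birth day 2 (replicates 4 to 6), so replicate 6 lay under its controls. Levels of vit-2 followed, at 10.77, 10.08 and 10.72 log2 in replicates 1, 4 and 5 and 8.59, 7.22 and 8.57 in replicates 2, 3 and 6.

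Histone genes and part of the small RNA genes also rose in F5 mutants. Histone genes had 17 rises and 0 falls among 28 (19 and 0 adjusted over the list alone), with his-59 at 0.91 ± 0.098 (SE) and his-38 at 0.67 ± 0.086 and a median of 0.26; camera adjusted p = 6.54e-06, and adjusted p = 0.16 with an estimated correlation. Small RNA pathways had 15 rises and 3 falls among 32 (18 and 3 adjusted over the list alone), with rrf-2 up by 0.68 ± 0.11 and the Argonaute gene alg-1 down (-0.69 ± 0.13); camera adjusted p = 8.06e-04, and adjusted p = 0.98 with an estimated correlation. H3K4 methylation machinery had 7 rises, utx-1 first (0.44 ± 0.072), and wdr-5.1 as the only fall among 17 (7 and 1 adjusted over the list alone, camera adjusted p = 0.198). Ribosomal protein genes had 3 rises and 0 falls among 66 (1 and 0 adjusted over the list alone, camera adjusted p = 0.412), with rpl-11.1 at 0.23 ± 0.061 and rpl-25.2 at 0.089 ± 0.031.

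Moulting cycle genes fell in F5 mutants, while most muscle and neuron genes were not called. Moulting cycle genes had 0 rises, 31 falls and 16 not called among 47 (0 and 31 adjusted over the list alone), with mlt-10 at -0.96 ± 0.13 (SE), sym-1 at -0.76 ± 0.13 and a median of -0.41; camera adjusted p = 6.99e-08, and adjusted p = 0.98 with an estimated correlation. Muscle genes had 0 rises, 13 falls and 33 not called among 46 (0 and 12 adjusted over the list alone), with the pharyngeal myosin genes myo-1 (-0.72 ± 0.13) and myo-2 (-0.73 ± 0.14); camera adjusted p = 0.0014, and adjusted p = 0.98 with an estimated correlation. Neuron had 2 rises, snb-1 first (0.44 ± 0.047), and 17 falls, the G protein gene goa-1 first (-0.57 ± 0.082), with 67 not called among 86 (1 and 16 adjusted over the list alone); camera adjusted p = 0.0275, and adjusted p = 0.98 with an estimated correlation. Pharyngeal gland and cells had 0 rises and 7 falls among 26 (0 and 7 adjusted over the list alone, camera adjusted p = 0.157), with pqn-13 at -1.07 ± 0.13 and phat-4 at -0.84 ± 0.16. Intestine had 9 rises and 19 falls among 52 (10 and 19 adjusted over the list alone, camera adjusted p = 0.128), with asp-1 at -0.30 ± 0.038. Cuticle collagens had 34 rises and 14 falls among 110 (35 and 16 adjusted over the list alone, camera adjusted p = 0.051), with col-91 at 0.86 ± 0.14 and col-142 at 0.98 ± 0.17.

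Of the stress and metabolic lists of F5 mutants, camera called DAF-16 up targets and glycolysis and central carbon. DAF-16 up targets had 13 rises and 2 falls among 25 (14 and 4 adjusted over the list alone), with the small heat shock gene hsp-16.2 at 2.52 ± 0.25 (SE) and the fatty acid desaturase gene fat-7 at 1.63 ± 0.18; camera adjusted p = 0.0010, and adjusted p = 0.21 with an estimated correlation. DAF-16 down targets had 5 rises, dod-23 among them (1.15 ± 0.27), and 3 falls, dod-17 first (-1.12 ± 0.12), among 15 (5 and 3 adjusted over the list alone, camera adjusted p = 0.832). Chaperones had 9 rises and 5 falls among 23 (10 and 5 adjusted over the list alone, camera adjusted p = 0.141), with hsp-60 down (-0.96 ± 0.095). Glycolysis and central carbon had 1 rise and 16 falls among 35 (1 and 16 adjusted over the list alone), with sucg-1 at -0.50 ± 0.071 and the glycolytic gene gpi-1 at -0.40 ± 0.056; camera adjusted p = 3.18e-04, and adjusted p = 0.98 with an estimated correlation. Lipid metabolism had 12 rises and 16 falls among 60 (14 and 19 adjusted over the list alone, camera adjusted p = 0.548), with the enoyl-CoA hydratase gene ech-6 at -0.46 ± 0.051. The respiratory chain had 9 rises, asb-1 of the ATP synthase first (0.61 ± 0.096), and 8 falls, ucr-2.3 first (-0.51 ± 0.067), among 37 (10 and 8 adjusted over the list alone, camera adjusted p = 0.945).

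Immune and signalling lists of F5 mutants had both signs. Detoxification had 14 rises and 15 falls among 85 (14 and 15 adjusted over the list alone, camera adjusted p = 0.723), with ugt-22 at -0.92 ± 0.086 (SE). Innate immunity had 16 rises and 15 falls among 75 (17 and 17 adjusted over the list alone, camera adjusted p = 0.626), with lys-10 and irg-4 at its ends. Insulin signalling had 5 rises, ins-37 first (1.07 ± 0.21), and 5 falls, akt-2 first (-0.44 ± 0.088), among 32 (5 and 5 adjusted over the list alone, camera adjusted p = 0.955). Dauer and developmental arrest had 6 rises and 5 falls among 35 (6 and 5 adjusted over the list alone, camera adjusted p = 0.481), with the AMP-activated kinase gene aak-2 at -0.55 ± 0.073. Longevity regulators had 1 rise and 6 falls among 30 (1 and 6 adjusted over the list alone, camera adjusted p = 0.169), with the FoxA gene pha-4 at -0.41 ± 0.099. Median, mean and test differed in sign in 3 lists, none of them called: H3K4 methylation machinery, insulin signalling and the respiratory chain.

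In total 6878 probe sets passed in F5 mutants, 3519 higher and 3359 lower. The higher share was 51.2%, against 39.6% with arrays centred on their medians and 45.9% with quantile normalization. The fit with an own mean per group and day called 2665 higher and 2576 lower on birth day 1, and 2347 and 1629 on birth day 2. Differences of the days had r = 0.823 across probe sets, the days fitted alone called 4540 and 4228, and 15 probe sets differed between the days. A fit on the means of each group and birth day called 62, and rpl-25.2 lost its call without any 1 of 3 single arrays. With the score of each array on the leading axis of spread among F5 mutant arrays as a covariate, a fit added after seeing the data, 4032 were called. The rises went from 26 to 12 in oocyte and eggshell genes, from 27 to 3 in sperm genes and from 33 to 16 in germline genes. They went from 17 to 2 in adult stage genes, from 6 to 0 in vitellogenins and from 15 to 7 in small RNA pathways (median 0.235 to 0.103). Smaller changes were from 13 to 12 in DAF-16 up targets and from 17 to 16 in histones. The falls went from 31 to 14 in moulting cycle genes, from 13 to 5 in muscle genes and from 16 to 7 in glycolysis and central carbon. The neuron list turned from 2 rises and 17 falls (median -0.084) to 13 rises and 3 falls (median 0.041). Rises and falls went from 9 and 8 to 13 and 2 in the respiratory chain, from 14 and 15 to 21 and 9 in detoxification and from 16 and 15 to 23 and 12 in innate immunity. Intestine went from 9 and 19 to 15 and 12. Other changes were from 12 and 16 to 12 and 7 in lipid metabolism and from 34 and 14 to 24 and 10 in cuticle collagens. Pharyngeal gland and cells went from 0 and 7 to 3 and 2 and longevity regulators from 1 and 6 to 2 and 2. The remaining lists changed by at most 3 members in a direction. The 6 dap labelling controls had median differences of 0.79 and 0.71 on the birth days, against 0.065 and 0.058 for the other 71.

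**Figure D2:**
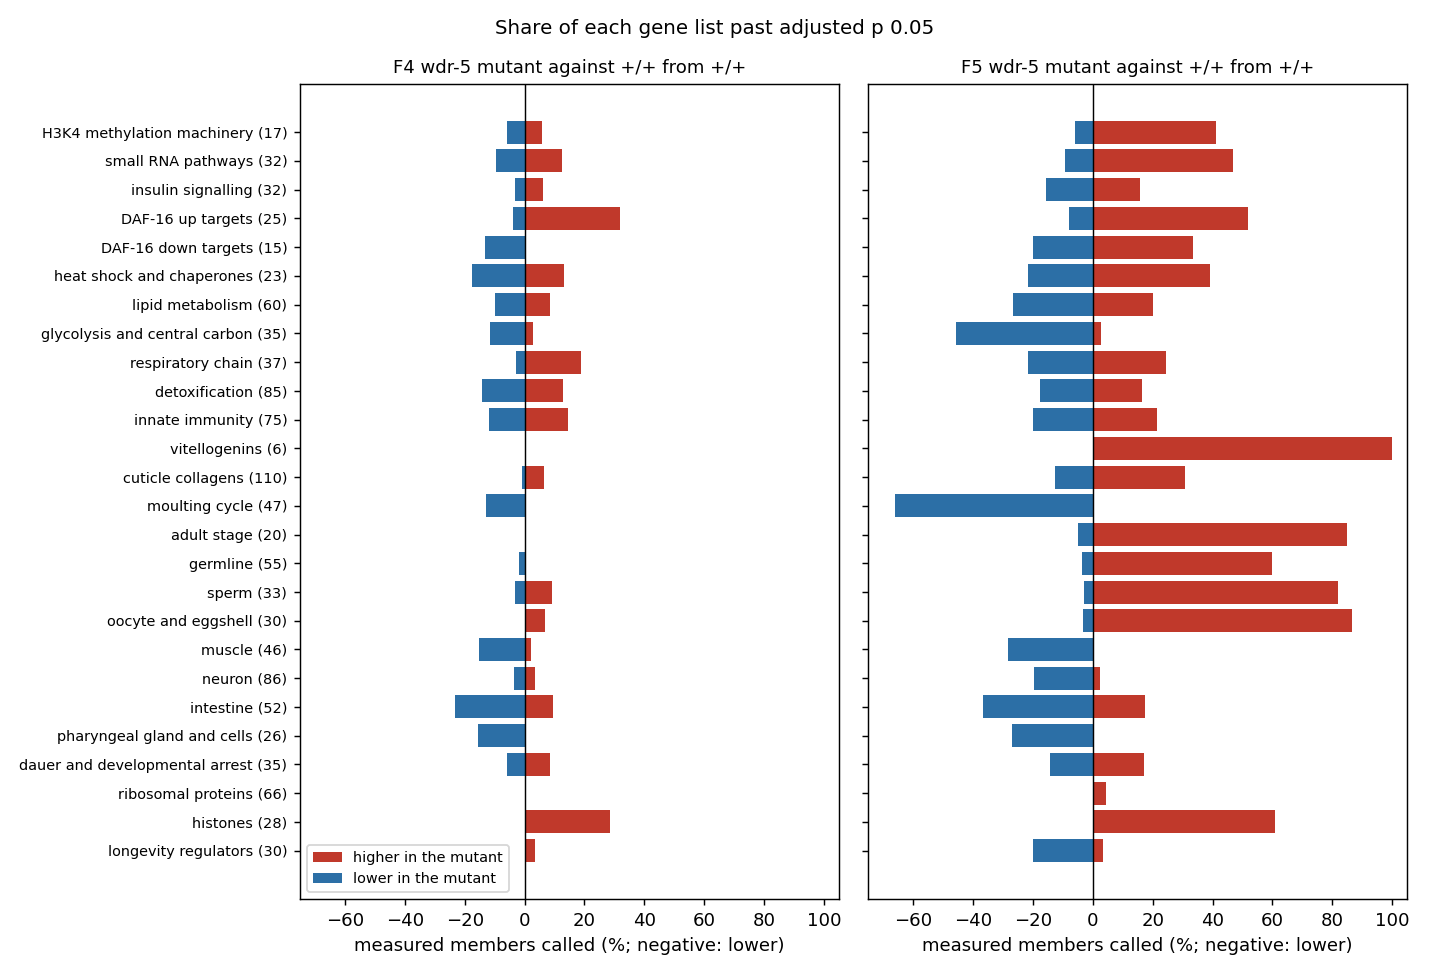
Percent of the measured members of each gene list (number in brackets) past an adjusted p of 0.05, higher to the right and lower to the left, in mutants against +/+ from +/+ of F4 (left) and F5 (right). In F5, 6 of 6 vitellogenins and 26 of 30 oocyte and eggshell genes were higher and 31 of 47 moulting cycle genes were lower; in F4 these counts were 0, 2 and 6, and a test of single probe sets between the generations called 2, or 0 to 4184 under the alternatives.

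**Figure D3:**
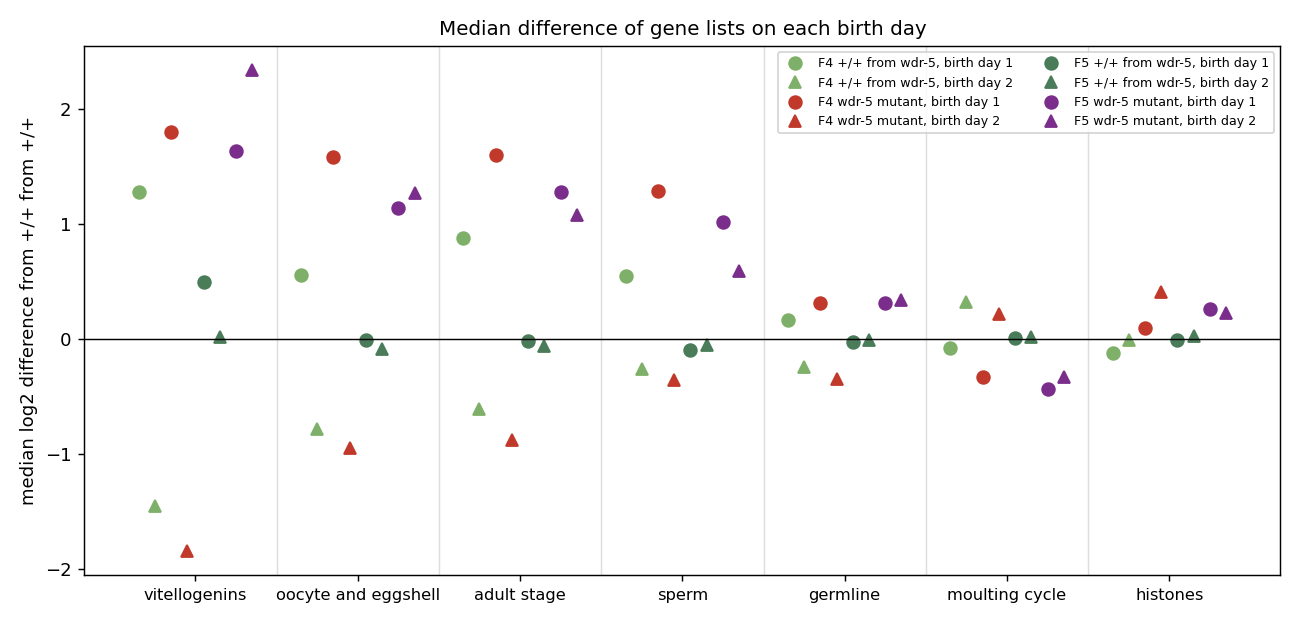
Median log2 difference from +/+ from +/+ of 7 gene lists on birth day 1 (circles) and birth day 2 (triangles) in 4 groups. Vitellogenin medians went from 1.80 to -1.84 in F4 mutants and from 1.28 to -1.45 in F4 +/+ from wdr-5, and were 1.64 and 2.34 in F5 mutants.

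Mutants were also compared with the wild-type descendants of mutants, which share the ancestry but not the genotype. In F4 the largest fitted rises were in lys-10 (3.41 ± 0.13, SE), W08E12.2 (2.36 ± 0.29), C01G10.5 (2.23 ± 0.37), C50F7.5 (2.11 ± 0.28) and far-3 (1.77 ± 0.19), and the largest falls in wdr-5.1 (-3.59 ± 0.14), asp-12 (-2.14 ± 0.20), Y49E10.4 (-1.79 ± 0.11), irg-4 (-1.64 ± 0.15) and F32D8.12 (-1.28 ± 0.11). In F5 the rises were led by lys-10 (3.26 ± 0.13), ule-3 (2.98 ± 0.74), col-81 (2.97 ± 0.71), D1054.10 (2.97 ± 0.77) and F53H4.2 (2.88 ± 0.72), and the falls by wdr-5.1 (-3.77 ± 0.15), irg-4 (-2.13 ± 0.16), Y49E10.4 (-1.97 ± 0.11), F42A10.7 (-1.53 ± 0.14) and fkb-8 (-1.47 ± 0.14). The lys-10 values of +/+ from wdr-5 lay under the 25th percentile of all 6 arrays in F4 and all 5 in F5, and those of F53H4.2 in 4 of 5, so the sizes of these rises are uncertain. The paralog wdr-5.3 differed by 0.35 ± 0.23 (SE, adjusted p = 0.37) in F4 and rose by 0.79 ± 0.25 (SE, adjusted p = 0.015) in F5, and wdr-5.2 by -0.021 ± 0.064 and -0.10 ± 0.068 without passing. The F5 rise of wdr-5.3 was not past the threshold without replicate 5 of the F5 mutants (0.65, adjusted p = 0.058). Histone genes had 11 rises and 0 falls among 28 in F4, with camera adjusted p = 3.28e-08 and adjusted p = 0.036 with an estimated correlation, and 16 rises and 1 fall in F5, with camera adjusted p = 1.40e-05 and adjusted p = 0.12 with an estimated correlation. These list tests against +/+ from wdr-5 were added later and adjusted as a family of their own. Camera called 10 lists in F4. Histones, oocyte and eggshell, respiratory chain, ribosomal proteins, innate immunity and DAF-16 up targets were higher, and moulting cycle, pharyngeal gland and cells, muscle and intestine lower. It called 13 in F5. Oocyte and eggshell, sperm, germline, histones, adult stage, DAF-16 up targets, small RNA pathways, vitellogenins and chaperones were higher. The moulting cycle, muscle, glycolysis and central carbon and neuron lists were lower. With an estimated correlation only histones in F4 were called. Counts were 2455 in F4 (1218 higher, 1237 lower) and 6294 in F5 (3080 higher, 3214 lower). The balance moved with the fit. In F4 it was 1561 higher and 1089 lower on birth day 1 alone, 2108 and 1726 with the stage axis and 1306 and 1502 with quantile normalization. In F5 it was 2010 and 1440 on birth day 1 alone, 1914 and 1412 with the stage axis and 2765 and 4169 with arrays centred on their medians. Between the birth days 498 probe sets differed in F4 and 4 in F5, and fits on the means of each group and birth day called 5 and 42.

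Mutant differences of the generations were set against each other. The cadmium-responsive gene cdr-4 was lower in F4 mutants (-0.94 ± 0.16, SE) and higher in F5 mutants (0.57 ± 0.16), a difference of -1.51 ± 0.23 (SE, adjusted p = 0.0034). The pud-4 gene differed by 0.042 ± 0.11 in F4 mutants and rose by 0.91 ± 0.11 in F5 mutants, a difference of -0.86 ± 0.15 (SE, adjusted p = 0.031), which lost its call without any 1 of 8 single arrays. These 2 probe sets were the only ones past the threshold with limma, and 2914 had an unadjusted p under 0.05. The next genes, asp-12 (-1.43 ± 0.28, SE), fat-7 (-1.34 ± 0.26) and C48B4.8 (-0.80 ± 0.16), had an adjusted p of 0.068. Other fits called far more: 2373 with array weights, 4184 on birth day 2 alone and 722 with an own mean per group and day. The count was 136 without replicate 6 of the F5 mutants and 1 without replicate 5 of F4 +/+ from +/+; 0 passed without a birth day term, where 1096 had an unadjusted p under 0.05.

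Probe sets called in both generations went the same way, except 1. Of the 992 probe sets higher in F4 mutants, 730 were higher in F5 mutants, where independent lists would share 167.8, and of the 1150 lower in F4, 751 were lower in F5, against 185.7. Opposite calls were 0 and 1 (cdr-4, -0.94 ± 0.16, SE, in F4 and 0.57 ± 0.16 in F5). The generations share no control arrays. Differences had r = 0.688 across probe sets, and by birth day F4 mutants of day 1 gave r = 0.835 and 0.83 with F5 mutants of the days, while those of day 2 gave -0.225 and -0.280.

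Whether descendants carried a fainter form of the mutant difference was examined by correlation across probe sets, which are not independent replicates. In F4 the measure cannot decide this, since neither difference repeated between the days (r = -0.383 for mutants and -0.616 for +/+ from wdr-5). In F5 these values were 0.823 and -0.131. Between birth days, with no shared array, r between +/+ from wdr-5 and mutant differences was -0.626 in F4 and -0.0715 in F5 (Spearman -0.479 and -0.0613). Without single arrays it ran from -0.648 to -0.573 in F4. In F5 it ran from -0.115 without replicate 1 of +/+ from wdr-5 to -0.00046 without replicate 2. It was -0.039 without replicate 5 of that group and -0.046 and -0.043 without replicates 2 and 4 of +/+ from +/+. Pooled over the days with shared controls, r was 0.217 in F4 and 0.052 in F5, where simulated unchanged groups gave 0.50 and 0.475. The pooled covariance was 0.0042 in F4 and 0.0012 in F5, against simulated 0.0057 in both generations. The simulated mutants held no difference, while real mutant differences can lower a pooled r. The simulated noise was the spread shared by all arrays. Differences of F5 +/+ from wdr-5 had an SD of 0.069 across probe sets, under their median standard error of 0.085, so this noise may be too wide. No conclusion is therefore drawn from the pooled values.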

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

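The contrasts between generations were fixed beforehand, while the tests of explanations in this part, the tests between birth days and of control probe sets, and the choice of deposited over day-centred values for outlying arrays came after the results were seen.

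In 10 of 347 groups of values of named genes (2.88%), 1 array lay far from the others of its group by Dixon's ratio, where chance gives about 1 in 20. With values centred on each birth day the count was 1 of 347. At most 3 arrays a day leave the ratio little room there, so this low count says little about outlying arrays. In F4 mutants, replicate 1 was highest for F32D8.12 (8.0, the others 7.58 to 7.65) and pqn-74 (8.60, the others 7.80 to 8.04), replicate 6 was highest for irg-4 (6.03, the others 5.19 to 5.49) and replicate 5 lowest for his-59 (7.09, the others 7.44 to 7.60). In F4 +/+ from +/+, replicate 2 was lowest for pqm-1 (7.43, the others 7.69 to 7.81) and highest for pha-4 (5.64, the others 4.94 to 5.16). In F4 +/+ from wdr-5, replicate 1 was highest for wdr-5.3 (7.14, the others 6.78 to 6.88). In F5 mutants, replicate 4 was lowest for F42A10.7 (6.57, the others 6.94 to 7.11) and replicate 1 highest for F32D8.12 (8.07, the others 7.30 to 7.49). In F5 +/+ from +/+, replicate 3 was highest for pha-4 (5.89, the others 5.49 to 5.63). These values span both birth days, whose value ranges differ.

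A difference between groups marked cdr-4 (-1.51) and pud-4 (-0.86), whose mutant differences differed between F4 and F5. The difference between the birth days was past the threshold in 377 probe sets for F4 +/+ from wdr-5, 6856 for F4 mutants, 498 for F4 mutants against +/+ from wdr-5, 2 for F5 +/+ from wdr-5, 15 for F5 mutants and 4 for F5 mutants against +/+ from wdr-5.

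The 77 control probe sets belong to no comparison of genes. Fitted with limma and adjusted over these 77 alone, 31 passed in F4 mutants against +/+ from +/+ (28 higher, smallest adjusted p = 0.044). In F4 mutants against +/+ from wdr-5 1 passed (adjusted p = 0.0036), and in F5 mutants against +/+ from +/+ 1 passed (adjusted p = 0.048). The 6 probe sets for dap, a transcript added before labelling, had median differences of 0.88 and 0.64 on the birth days in F4 mutants and 0.79 and 0.71 in F5 mutants. No explanation for this was tested.

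Oocyte and eggshell, sperm and adult stage genes of F4 +/+ from wdr-5 differed in opposite directions on the birth days. The r of the days was -0.616 over all probe sets (-0.637 to -0.561 without single arrays), and 1 of 100 splits gave as large a size of r. A difference in stage at harvest would put these differences on the leading axis of spread among F5 mutant arrays, and their r with that axis was 0.653 on day 1 and -0.677 on day 2. With the axis taken out, r of the days was -0.312 (-0.389 to -0.226), and 6 of 100 splits gave as large a size, so a difference in stage may account for part of the pattern and the rest stays open. An exchange of the +/+ labels on 1 birth day could also give opposite days. With the labels of either day exchanged 24 probe sets were called, and r of the mutant days went from -0.383 to 0.0083 for day 2 and to -0.126 for day 1. Exchanging day 2 gave 4396 calls for F4 mutants against +/+ from +/+ (2142 as labelled), 2032 against +/+ from wdr-5 (2455) and 4 for mutants between generations (2). Exchanging day 1 gave 2032, 4396 and 837. Both exchanges form the same sets of F4 +/+ arrays with the names swapped. The 24 calls and the counts of 4396 and 2032 are therefore mirror images and not separate outcomes. Without any exchange, taking out the stage axis turned r of the mutant days to 0.187. Taking out residual axes gave 0.224 to 0.302, and r of the +/+ from wdr-5 days was -0.151 without the first and second. The r of the mutant days therefore does not decide for an exchange. The 4 genes sax-2, fbxa-192, fbxa-193 and ztf-28 were called on both days of F4 with each day fitted alone. On day 2 of F5 these genes differed (0.45 ± 0.099, -0.51 ± 0.12, -0.33 ± 0.11 and -0.48 ± 0.11, SE, adjusted p from 0.62 to 0.9999) in the direction the day 2 labels of F4 give. On day 1 of F5 they differed by -0.070 to 0.032. These genes were chosen for the pattern and none passed in F5, so they decide nothing, and over all probe sets r of day 2 of F4 with day 2 of F5 was 0.119. An exchange on either day, and ancestry itself, stay open.

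Oocyte, sperm and adult stage genes rose in F5 mutants. The mutant animals may have been older at harvest: their differences had r = 0.618 on day 1 and 0.541 on day 2 with the same axis, which holds 72.1% of the spread among F5 mutant arrays. On this axis replicates 1, 4 and 5 (26.7 to 38.4) stood apart from replicates 2, 3 and 6 (-22.3 to -14.4), and replicate 6 lay under its same-day controls (-12.602 to -9.99), so not all mutant arrays lay higher on it. With the axis as a covariate, rises went from 26 to 12 in oocyte and eggshell genes, from 27 to 3 in sperm genes and from 17 to 2 in adult stage genes, while the median of the oocyte and eggshell list went from 1.17 to 0.26 (quartiles 0.075 to 0.45). Histones had 17 rises before and 16 after, with a median of 0.261 before and 0.272 after (quartiles 0.18 to 0.49). In F4 mutants they had 8 and 11 rises, with a median of 0.20 before and 0.225 after (quartiles 0.034 to 0.42), and on birth day 2, where the axis ran the other way, a median of 0.413 (quartiles -0.022 to 0.72). This argues against age, as far as the axis follows it, as the whole source of the histone rise; an effect of age off this axis stays open. A faster development of the mutants and a different time of collection cannot be told apart here, since no age at harvest was measured.

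Variants near wdr-5.1 on chromosome III could have come along with the mutation from another background and act on their own genes. Of the genes called in F5 mutants 85.1% lie on other chromosomes, and 84.7% in F4 mutants, which argues against such variants as the whole source of the mutant differences. A linked variant in a regulator of genes elsewhere is not touched by this and stays open. Among the 100 genes on each side of wdr-5.1, 10 percent were called in F4 mutants against 10.2 percent of the other genes (Fisher's exact test, adjusted p = 1), and 35 against 32.5 percent in F5 mutants (adjusted p = 0.52). Windows of 25, 50 and 200 genes per side, added later, gave 18, 15 and 14.25 percent in F4 and 38, 36 and 35.25 percent in F5, with adjusted p from 0.074 to 0.52. Unlinked background variants were not tested.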

How the results depend on the processing

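The fits on means of a group and birth day, with an own mean per group and day, with axes of spread as covariates and with 1 probe set per gene were chosen after the results were seen, and the other alternatives beforehand. Replicate numbers did not pair arrays: of 34 pairs with the same number 11 correlated over 0.1 (r from -0.295 to 0.317), and 11 of 35 arrays correlated best with their own number. The number of arrays limits the precision, and signal over background was not assessed.

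The counts of 0 for F4 and F5 +/+ from wdr-5 and for their difference stayed 0 with limma under all alternatives that used both birth days, where 94 to 1351 probe sets in F4 and 19 to 680 in F5 had an unadjusted p under 0.05 with all arrays. All counts stayed within 1.5 times under the other deposited table (identical values), median centring, no intensity trend and 1 probe set per gene. The replicate block called 1 probe set for mutants between generations, and its other counts stayed within 1.5 times.

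Birth day 1 alone called 9 in F4 +/+ from wdr-5, 6335 in F4 mutants, 2 in F5 +/+ from wdr-5, 4540 in F5 mutants, 3450 in F5 mutants against +/+ from wdr-5, 20 for mutants between generations and 39 lists. Birth day 2 alone called 10 in F4 +/+ from wdr-5, 1254 in F4 mutants against +/+ from wdr-5, 4228 in F5 mutants, 4184 for mutants between generations and 42 lists. Of the 22 lists 16 were shared with each day. Fewer arrays enter these fits. In F4 mutants the difference from +/+ from +/+ varied between the days in 6856 probe sets. A fit over both days averages such differences, also where their signs are opposite. How much of the higher counts this explains was not tested.

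Without a birth day term 409 passed in F4 mutants, 599 in F4 mutants against +/+ from wdr-5, 2776 in F5 mutants, 2412 in F5 mutants against +/+ from wdr-5 and 0 for mutants between generations, where limma gave 1096 at an unadjusted p under 0.05. Only the groups compared left 913 in F4 mutants. For mutants between generations, quantile normalization called 21, leaving out dim probe sets 20 and array weights 2373; the cause was not tested.

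Means of a group and day, with few degrees of freedom, called 11 in F4 mutants, 5 in F4 mutants against +/+ from wdr-5, 62 in F5 mutants, 42 in F5 mutants against +/+ from wdr-5 and 0 for mutants between generations (468 at an unadjusted p under 0.05 with limma). An own mean per group and day called 3578 in F4 mutants and 722 for mutants between generations. With the stage axis as a covariate the counts were 3768 and 3834 for F4 mutants against +/+ from +/+ and from wdr-5, 4032 and 3326 for F5 mutants, and 1.1e+02 for mutants between generations (46 higher, 61 lower); 3126 of the 4032 were shared with the 6878. The first residual axis gave 110 for mutants between generations, and the first and second gave 1.8e+02 there (100 higher, 79 lower) and 3780 in F4 mutants; the cause was not tested.

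The correlation of F4 +/+ from wdr-5 with mutants was reversed to 0.217 when pooled over days with shared controls, and was -0.479 as Spearman's rho; in F5 the pooled value was 0.052. Shared controls raise a pooled r by construction. Camera with an estimated correlation called 0 lists, and fry called 16.

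Leaving out single arrays gave 1403 to 2812 for F4 mutants, lowest without replicate 2 of F4 +/+ from +/+, highest without replicate 4, and 1421 without replicate 1. For mutants between generations the range was 1 to 136, and 13 of 24 arrays moved the count past 1.5 times, with 99 without replicate 2 of F4 +/+ from +/+, 71 without replicate 2 of F4 mutants, 17 without replicate 4 of F5 mutants and 136 without replicate 6. Other counts stayed within 1.5 times.

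For single genes, 3255 of 3428 values kept direction and side of the threshold, 63 lost a call, 55 gained a call and 55 reversed. Without single arrays, calls were lost by dpy-17, akt-2, utx-1 and col-176 in F4 mutants, rpl-25.2 in F5 mutants, wdr-5.3 in F5 mutants against +/+ from wdr-5 and pud-4 between generations. Calls were gained by htp-2 (without any 1 of 5 arrays), pha-4 (3), rla-1 (3) and rpl-15 (1) in F4 mutants and by fat-7 (7), asp-12 (6) and C48B4.8 (6) between generations. Reversals on birth day 1 alone were wdr-5.3 (0.36), wdr-5.1 (0.012) and wdr-5.2 (-0.068) in F4 +/+ from wdr-5, wdr-5.2 in F4 mutants (-0.15), and wdr-5.3 (-0.012), wdr-5.1 (-0.037) and wdr-5.2 (0.019) in F5 +/+ from wdr-5. Between generations they were wdr-5.3 (0.37), wdr-5.1 (0.049) and wdr-5.2 (-0.087) for +/+ from wdr-5 and wdr-5.3 (0.61), wdr-5.1 (-0.016) and wdr-5.2 (-0.027) for mutants. On birth day 2 alone, F4 mutants reversed for wdr-5.3 (-0.64), vit-1 (-0.74), vit-2 (-1.83), msp-76 (-0.76), oma-1 (-0.60), htp-2 (-0.14) and pha-4 (0.022), F4 mutants against +/+ from wdr-5 for wdr-5.3 (-0.13) and wdr-5.2 (0.044), and +/+ from wdr-5 between generations for dpt-1 (-0.014). The stage axis reversed vit-2 in F4 mutants (-0.055). Quantile normalization reversed wdr-5.2 in F4 mutants against +/+ from wdr-5 (0.0048) and wdr-5.1 in F5 +/+ from wdr-5 (-0.0026), and the replicate block wdr-5.3 in F5 +/+ from wdr-5 (-0.028). None of the reversed values had passed the threshold, and the cause was not tested.

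Without single arrays, differences that changed sign ranged in F4 +/+ from wdr-5 from -0.25 to 0.088 for wdr-5.3, -0.10 to 0.0042 for wdr-5.1 and -0.0027 to 0.078 for wdr-5.2. In F4 mutants they ranged from -0.019 to 0.057 for wdr-5.2 and -0.029 to 0.75 for vit-2, and against +/+ from wdr-5 from -0.065 to 0.015 for wdr-5.2. In F5 +/+ from wdr-5 they ranged from -0.061 to 0.079 for wdr-5.3, -0.036 to 0.037 for wdr-5.1 and -0.040 to 0.025 for wdr-5.2. Between generations they ranged from -0.27 to 0.070 for wdr-5.3 in +/+ from wdr-5 and -0.014 to 0.30 for wdr-5.1 in mutants.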

Other observations

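All tests in this part, and the genes named in it, were chosen after the results were seen.

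Other splits of the arrays within birth day, 100 per comparison with the real one included, were counted against the real calls. As many calls were given by 2 of 100 splits for F4 mutants against +/+ from +/+ (2142 called, highest other 5131). It was 1 of 100 for F4 mutants against +/+ from wdr-5 (2455, highest other 300). It was also 1 of 100 for F5 mutants against +/+ from +/+ (6878, highest other 4069) and against +/+ from wdr-5 (6294, highest other 5418). Adjusted over the 8 comparisons by Benjamini-Hochberg, these shares were 0.04 for F4 mutants against +/+ from +/+ and 0.027 for the others. A chance assignment of single arrays was thus unlikely to give these counts. The splits cannot exclude chance differences shared by all arrays of a group and birth day, since they exchange single arrays. In F4 mutants against +/+ from +/+ the difference varied between the days in 6856 probe sets. For mutants between generations 4 of 100 splits gave as many as the 2 calls (adjusted share 0.064, highest other 2427), and the count was 0 without a birth day term, 1 with the replicate block and 1 to 136 without single arrays, so no conclusion on chance is drawn from these 2 probe sets. Counts of 0 are reached by every split, so the splits decide nothing for F4 +/+ from wdr-5 (0, 100 of 100, highest other 1060), F5 +/+ from wdr-5 (0, 100 of 100, highest other 0) and their difference (0, 100 of 100, highest other 0). The highest split of F5 mutants against +/+ from +/+ (4069 calls) exchanged 3 arrays on day 1 and 2 on day 2. That against +/+ from wdr-5 (5418 calls) exchanged 2 and 3. Both are nearly the real groups with the names swapped, and so no sign of another structure. The split with 5131 calls in F4 mutants exchanged 3 and 1, so it reversed day 1 and mostly kept day 2. The splits with 2427 and 1060 calls exchanged 3 and 1, and 2 and 1, and no conclusion is drawn from them. The score on the stage axis differed between the sides of the highest split by -33 in F4 mutants, against 7.82 in the real groups, and by -52.2 against -21.5 between generations. In F5 mutants it differed by -33.4 in the highest split against 29.3 in the real groups, and against +/+ from wdr-5 by -32.8 against 30.9. The sign was thus reversed and the size close to that of the real groups. For the gene lists chance cannot be excluded, since 88 of 100 random assignments called as many lists as the real 22 (median 35, highest other 58). For lists of mutants against +/+ from wdr-5 it cannot be excluded either at the preset correlation (23 called, 18 of 100 as many, highest other 31). At an estimated correlation, where histones in F4 were the 1 call, 3 of 100 assignments called as many (highest other 1). Adjusted over the 3 counts of lists this share was 0.09, so no conclusion is drawn.

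Within 1 birth day only 10 splits exist, too few for a share under 0.05. The real count and the highest other were 9 and 1 for F4 +/+ from wdr-5 on day 1 (1 of 10 as large), 10 and 0 on day 2 (1 of 10), 6335 and 0 for F4 mutants on day 1 (1 of 10), 2495 and 0 on day 2 (1 of 10), 4540 and 0 for F5 mutants on day 1 (1 of 10), and 4228 and 643 on day 2 (1 of 10). For F5 +/+ from wdr-5 on day 2 they were 0 and 0 (10 of 10), as any split gives at least 0.

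In F4 +/+ from wdr-5, the fit with an own mean per group and day called more probe sets on each day than that day fitted alone. With each day fitted alone, 12 genes were called on a single day or on both. The other day had the opposite sign in 10 and a size under 0.1 in 3, which were wago-10 (0.61 and 0.044), F33D4.6 (0.019 and 0.59) and F28E10.1 (-0.86 and 0.037). The F-box gene fbxa-192 differed by 1.1 on day 1 and -0.98 on day 2, fbxa-193 by 0.91 and -0.53, ztf-28 by 0.69 and -0.64 and sax-2 by -0.71 and 0.62, each called on both days. The small heat shock gene sip-1 differed by 1.02 and -1.03, called on day 1 only. In F5 +/+ from wdr-5 the collagen IV gene let-2 differed by 0.64 on day 1 and -0.14 on day 2.

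The 11 probe sets that a fit on means of a group and birth day called in F4 mutants belong to wdr-5.1, lys-10, Y49E10.4, dod-3, C50F4.6, F32D8.12, F42A10.7, scl-2, ZK218.5 and pgp-9. Among them F32D8.12 entered more than once, with the same values.

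Few genes of the X chromosome rose in F5 mutants: 6.42% of 2338 X-linked genes against 19.8% of 14452 autosomal genes (Fisher's exact test, two-sided, p = 3.76e-67, with genes not independent). Falls were at 26.5% and 13% (Fisher's exact test, p = 1.04e-60). In F4 mutants rises were at 3.42% and 5.33% (p = 5.67e-05) and falls at 6.46% and 4.91% (p = 0.00203, both by Fisher's exact test). No explanation for this was tested. With the stage axis as a covariate, rises in F5 were at 6.89% and 13.1%.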
